A study of Mus musculus with 32 samples.

How the data were processed

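Total RNA from the cardiac ventricle of mice was measured on 2 types of Affymetrix expression array, called here the first and the second array type, which carry different probe sets. Each type was used for 5 wild type samples, 8 samples of mice with a cardiac specific AT1 transgene and cardiac hypertrophy, and 3 samples of such mice in cardiac failure, 32 arrays in all. The labels do not spell out AT1, which in cardiac work usually stands for the angiotensin II type 1 receptor. They give no age, sex or strain and do not say that samples of a group came from separate animals, so p-values measure the spread between these samples, part of which may be technical.

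The deposited values are intensities on a linear scale, 1 per probe set, with 1 as the lowest value on both array types and 10665 and 11877 as the highest. How the authors scaled or summarised these deposited intensities is not given in the sources used here. Trimmed means of the arrays varied by 4.82% (coefficient of variation) on the first type and 3.31% on the second. Medians varied by 6.60% and 4.65%. The rule fixed beforehand asked that medians or trimmed means vary by less than 5%, so the values were used as deposited. The medians of the first type were above this limit. Values below the 20th percentile of an array type (39.5 and 27.5) were raised to it before taking log2, which understates changes of dim probe sets. A probe set was tested when it reached its own array's median in at least 3 arrays of the type and was not a control, which left 6980 of 12488 and 7004 of 12477 probe sets. Arrays give no counts, and their number limits the precision: the median standard error of a log2 change was 0.13 for hypertrophy against wild type and 0.17 for failure against wild type on both types.

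Each array type was fitted separately with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 model over all 16 arrays so that the 3 groups share an estimate of spread. The 3 comparisons were adjusted by the Benjamini-Hochberg method per array type and comparison, with a threshold of 0.05. Adjusted p-values of genes below are from this limma fit, and a change past the threshold is called. Figures were drawn with matplotlib 3.10.9. The fit was tested on simulated data with 200 changed probe sets, drawn independently from normal distributions with each probe set's mean and spread. Such data hold no correlation between probe sets and no array of poor RNA, so the shares below are best cases. A log2 change of 1 was recovered for 98.0% of them on the first array type in hypertrophy against wild type, 86.0% in failure against wild type and 90.0% in failure against hypertrophy. On the second type the shares were 93.0%, 84.0% and 86.5%. False calls made up 2.62% to 6.25% of the calls at this change and 3.86% to 7.44% at a change of 2, in some fits above the 5% that the threshold stands for.

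Probe sets were named from the platform annotation, with symbols updated through gene identifiers and synonyms to those of GRCm38.p6, which changed 12 and 20 of them. On the first type 10833 probe sets had 1 gene, 396 several and 1193 none, and on the second 10581, 178 and 1652; gene identifiers matched for 10817 and 10550. A gene is represented by its probe set of highest mean, on the first array type where it is there. In all, 33 gene lists were fixed, and 30 had at least 5 genes among those tested on the first type. They were tested there with camera at a preset inter-gene correlation of 0.01, adjusted over the 90 tests, and again with an estimated correlation, with fry, and by exact permutation of the list's mean per array; all tests were two-sided. Counts of called list members also cover members measured only on the second type, which are not part of these tests.

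The genes named below follow a rule with 3 parts: markers always named; the largest changes past the threshold without overlap between groups, or the smallest p-values where none passed; and up to 4 members of each list that passed its test. Predicted genes without a proper symbol, such as Gm5907 and Gm4788, and probe sets without a single gene name were skipped in the second part. The first part is Nppa, Nppb, Acta1, Myh7, Myh6, Atp2a2, Agtr1a and Agtr1b, the last of which had no tested probe set. The design, lists, rule and most alternatives were fixed before the data were examined. These alternatives were quantile and median scaling, other floors and filters, a variance trend with robust estimation, array weights, only the groups compared, the replicate number as a block, leaving out each array, and adjustment over both array types. Chosen after seeing the data were the fits without 2 hypertrophy arrays of low Gapdh ratio, those with the Gapdh ratio, Actb ratio or Xist signal as a covariate, the permutation of list means, and the rearranged residuals and divided wild type arrays for calls shared by 2 comparisons.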

Results

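The series measured ventricular transcripts in wild type mice and in mice carrying a cardiac AT1 transgene, sampled in hypertrophy or in failure. On each array type there were 5 wild type, 8 hypertrophy and 3 failure arrays. Median signals ranged from 91.8 to 121 on the first array type and from 69.3 to 80.6 on the second. Hypertrophy replicates 6 and 7 stood apart in the Gapdh control on the first type. The signal of the 5' Gapdh probe set was 0.468 and 0.0487 of the 3' one, against 0.889 ± 0.0543 (SD, n = 5) in wild type. The same ratio of Actb was 0.960 ± 0.173 (SD, n = 3) in failure, 0.701 ± 0.204 (SD, n = 8) in hypertrophy and 0.623 ± 0.0819 (SD, n = 5) in wild type. In hypertrophy replicate 6 the Actb ratio was 0.563, within the wild type range of 0.545 to 0.752, and in replicate 7 it was 0.357, below that range. Xist, the RNA of the inactive X chromosome, exceeded the Y-linked Eif2s3y in 2 of 5 wild type, 4 of 8 hypertrophy and 2 of 3 failure arrays of the first type. Failure replicate 3 is the failure array in which it did not, at 14.3 against 43.7, and both hypertrophy arrays of low Gapdh ratio are also among those in which it did not.

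**Figure D1:**
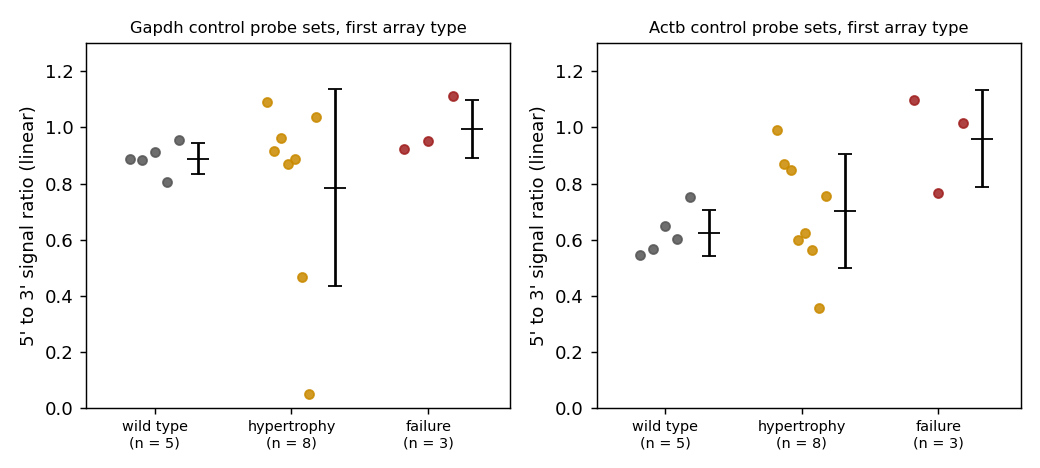
Ratio of 5' to 3' control probe set signal (linear axis) for Gapdh and Actb on each array of the first type, with mean and SD per group beside the points. Hypertrophy replicates 6 and 7 lie at 0.468 and 0.0487 for Gapdh.

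The first comparison set hypertrophy against wild type. A probe set for Styx, which encodes a phosphatase-like protein without catalytic activity, rose by 6.08 ± 0.15 (log2, SE), with signals of 1930 ± 301 (SD, n = 8) in hypertrophy and 13.2 ± 12.7 (SD, n = 5) in wild type. Because 4 of the 5 wild type arrays were below the floor, this is at least 67.8-fold higher (adjusted p = 2.5e-14). Slc13a1, a sodium and sulfate cotransporter, rose by 2.22 ± 0.20 (log2, SE), from 225 ± 38.9 (SD, n = 5) to 1072 ± 309 (SD, n = 8), with adjusted p = 7.0e-06. Vgll4, a cofactor of TEAD transcription factors, rose by 0.82 ± 0.14. Med28, a subunit of the Mediator complex, changed by -0.90 ± 0.12 (log2, SE), which was a signal of 168 ± 24.5 (SD, n = 8) against 315 ± 49.9 (SD, n = 5). Acat1, a mitochondrial thiolase, fell to 82.5 ± 16.3 (SD, n = 8) from 164 ± 25.9 (SD, n = 5). In each of these 5 probe sets all 8 hypertrophy arrays lay on one side of all 5 wild type arrays, which the rule that named them required. Over all 7004 probe sets of this type the groups did not overlap for 0.70%, against 0.155% by chance.

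**Figure D2:**
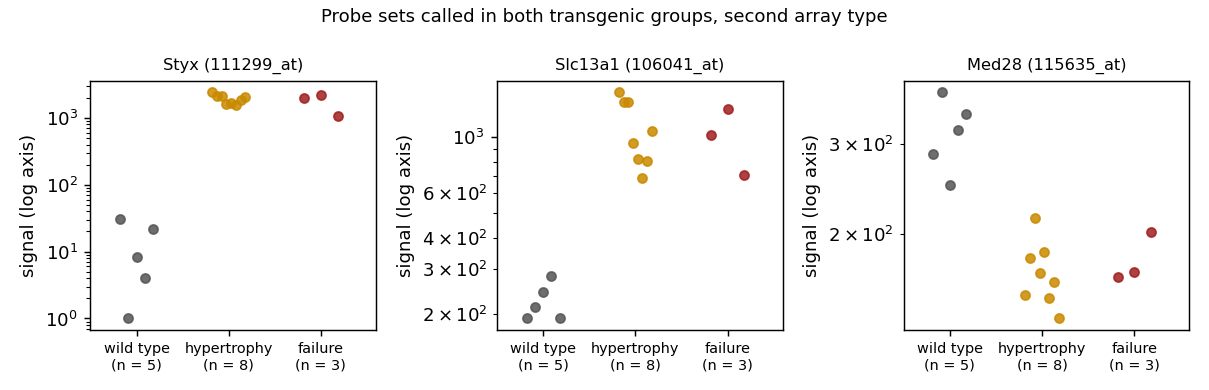
Signal (log axis) of 3 probe sets on every array of the second type, 1 point per array. All 11 transgenic arrays lie above the 5 wild type arrays for Styx and Slc13a1, and below them for Med28.

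In all, 12 of 7004 probe sets passed on the second array type, 10 higher and 2 lower. There 684 had an unadjusted limma p under 0.05, against 350 by chance. Median scaling gave 9 higher and 4 lower. On the first type none of 6980 passed in limma, and 312 had an unadjusted p under 0.05, against 349 by chance; the smallest adjusted p was 0.388. Without hypertrophy replicates 6 and 7, chosen after seeing the data, the second type gave 7 calls, and Vgll4, at 0.72 (log2), was no longer called (adjusted p = 0.0549). Leaving out hypertrophy replicate 1 gave 25 calls there and replicate 3 gave 5 (and 1 on the first type), while leaving out any 1 wild type array gave 6 or 7 and ended the Acat1 call, with its change between 0.931 and 1.06 times that with all arrays.

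On the first type the 6 smallest p-values, none past the threshold, belonged to Chil1, Phf7, Agtrap, Ext1, Mrpl42 and Ckap4. Agtrap, the protein that binds the angiotensin receptor, had a log2 difference of 0.47 ± 0.11 (SE), with adjusted p = 0.590, and its probe set on the second type -0.37 ± 0.12 (adjusted p = 0.349), the opposite direction. The markers of cardiac stress were not called. The natriuretic peptide genes Nppa and Nppb differed by -0.11 ± 0.42 and -0.03 ± 0.29, the skeletal actin gene Acta1 by 0.75 ± 0.38 and the beta myosin heavy chain gene Myh7 by 0.17 ± 0.10 in its brighter and 0.77 ± 0.18 in its dimmer probe set (log2, SE). The alpha myosin gene Myh6 differed by -0.0025 ± 0.08, the calcium pump gene Atp2a2 by 0.04 ± 0.07 and the receptor gene Agtr1a by -0.20 ± 0.14. Leaving out 1 array turns the sign for Nppa (-0.31 without wild type replicate 2 to 0.073 without replicate 4), Nppb (-0.24 without wild type replicate 5 to 0.13 without hypertrophy replicate 1) and Myh6 (-0.033 and 0.029 without hypertrophy replicates 2 and 1), so none of them has a direction. Quantile scaling gave 0.26 for the brighter Myh7 probe set and 0.15 for Atp2a2, which was 0.020 without wild type replicate 1 and 0.028 without hypertrophy replicate 3.

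Among the gene lists, respiratory chain and ATP synthase genes had a median log2 change of -0.18 (camera, adjusted p = 1.1e-08 and adjusted p = 0.724 with an estimated correlation), and 46 of 48 measured members were negative, none of them called or past the threshold adjusted over the list alone. Uqcrc2, a subunit of complex III, differed by -0.50 ± 0.19, Atp5d by -0.27 ± 0.12, Atp5c1 by -0.21 ± 0.11 and Ndufs7 by -0.28 ± 0.18 (log2, SE). Glycolysis genes had a median of -0.18 (adjusted p = 4.3e-05 and adjusted p = 0.724 with an estimated correlation), with 0 of 20 called and 0 adjusted over the list alone. Its members Eno3 and Ldhb both differed by -0.38, the glucose transporter gene Slc2a4 by -0.52 ± 0.25 (-0.30 without hypertrophy replicates 6 and 7) and Pfkp by 0.09 ± 0.12 (-0.025 without wild type replicate 5). Extracellular matrix genes had a median of 0.08 (adjusted p = 0.0345 and adjusted p = 0.950 with an estimated correlation), with 0 of 32 called and 0 adjusted over the list alone. Mgp differed by 0.48 ± 0.19, Mmp2 by 0.30 ± 0.12, Col18a1 by 0.19 ± 0.10 and Thbs4, on the second type and outside the test, by -0.20 ± 0.23 (-0.068 and -0.11 without hypertrophy replicates 1 and 2). The respiratory chain mean per array differed by -0.19 with an exact permutation p of 0.149. Hypertrophy arrays spanned 10.12 to 10.86 for this list and 7.59 to 8.67 for the matrix list, around the wild type ranges of 10.51 to 10.84 and 7.94 to 8.31, and for glycolysis 9.27 to 10.01 against 9.76 to 10.04. The other 27 lists did not pass, with medians from -0.14 to 0.07. Hypertrophy replicate 1, whose median signal of 91.8 was the lowest of its type, also had the lowest mean of both metabolic lists.

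**Figure D3:**
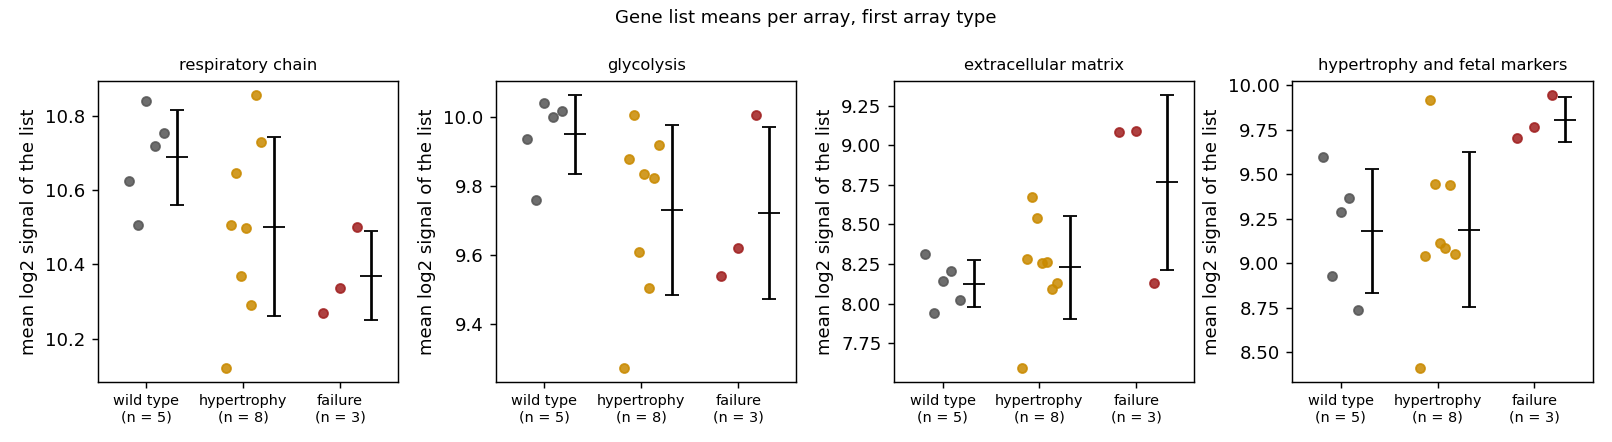
Mean log2 signal of 4 gene lists on each array of the first type, with group mean and SD beside the points. For the matrix list failure replicate 3 lies at 8.13 and failure replicates 1 and 2 at 9.08 and 9.09.

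The second comparison set failure against wild type. Myh7, the slow myosin heavy chain of fetal and stressed mouse ventricle, rose by 1.81 ± 0.23 (log2, SE) in 1 probe set, with signals of 3569 ± 677 (SD, n = 3) against 1049 ± 326 (SD, n = 5) and adjusted p = 0.00374. Its brighter probe set differed by 0.61 ± 0.13 without passing (adjusted p = 0.0752), and both can also bind transcripts of related myosins. Kif5b, a kinesin heavy chain below the floor in 2 of 5 wild type arrays, rose by 2.64 ± 0.43, the transcription factor gene Cebpd by 1.34 ± 0.24, Agtrap by 0.81 ± 0.14, Plp2 by 0.68 ± 0.12 and the nonmuscle myosin gene Myh14 by 0.65 ± 0.12 (log2, SE). Hgd, an enzyme of tyrosine breakdown, changed by -1.05 ± 0.17. A second Agtrap probe set, on the second array type, differed by -0.37 ± 0.16 without passing (adjusted p = 0.336), so the probe sets of this gene disagree.

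On the second array type Styx rose by 5.89 ± 0.19, at least 59.2-fold, Synpo2l by 2.51 ± 0.44 and Zfp982 by 2.32 ± 0.41 (log2, SE). Tanc2, at the floor in 1 failure array, changed by -1.66 ± 0.35, the adaptor gene Dok4 by -0.88 ± 0.17 and Rab3gap1 by -0.85 ± 0.15. Also higher were Slc13a1 by 2.13 ± 0.25, the actin-binding Xirp2 by 1.48 ± 0.27, the microtubule-associated Clip1 by 1.69 ± 0.33 and the receptor gene Tgfbr1 by 0.80 ± 0.16; of these Slc13a1, Clip1 and Tgfbr1 fall outside the rule and were chosen after their values were seen.

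In all, 10 probe sets passed on the first type, 9 higher and 1 lower, and 25 on the second, 20 higher and 5 lower. An unadjusted limma p under 0.05 was found for 746 and 854, against 349 and 350 by chance. Quantile scaling gave 20 higher and 10 lower on the first type and 20 and 15 on the second; median scaling gave 17 and 15, and 17 and 16. The arrays of the groups did not overlap for 13.3% and 13.8% of probe sets, against 3.57% by chance. On the first type, leaving out any 1 wild type array or failure replicate 1 or 2 left 0 to 3 calls, while leaving out failure replicate 3 gave 51 and hypertrophy replicate 1 or 7 gave 30 and 28. On the second type 1 wild type array fewer left 6 to 14 calls, failure replicate 1 or 2 fewer left 5 and 4, and hypertrophy replicates 4, 6, 1 and 7 left out gave 12, 13, 79 and 57. Without hypertrophy replicates 6 and 7, chosen after seeing the data, the counts were 34 and 70. Leaving out hypertrophy arrays does not alter the failure changes, only the shared estimate of spread, so the counts do not measure the size of the failure effect. Of the genes named by the rule, Styx kept its call without each array, Myh7 lost it without failure replicate 1, and each of the others lost it without failure replicate 1 and without failure replicate 2. Where 1 failure array fewer ended a call, the change was 0.781 to 1.15 times that with all arrays.

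The other markers did not pass. Nppa differed by 1.26 ± 0.54 (adjusted p = 0.410), Nppb by 1.04 ± 0.38 (adjusted p = 0.319) and Acta1 by 1.34 ± 0.49 (adjusted p = 0.326), with all 3 failure arrays above all 5 wild type arrays in each. Myh6 differed by -0.09 ± 0.11, Atp2a2 by 0.08 ± 0.09 and Agtr1a by -0.27 ± 0.17. Quantile scaling turns the sign for Atp2a2. Agtr1a was -0.12 without failure replicate 1 and -0.025 with the Actb ratio, Myh6 -0.058 without failure replicate 2 and -0.21 with quantile scaling, and Atp2a2 0.035 and 0.12 without failure replicates 1 and 3.

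**Figure D4:**
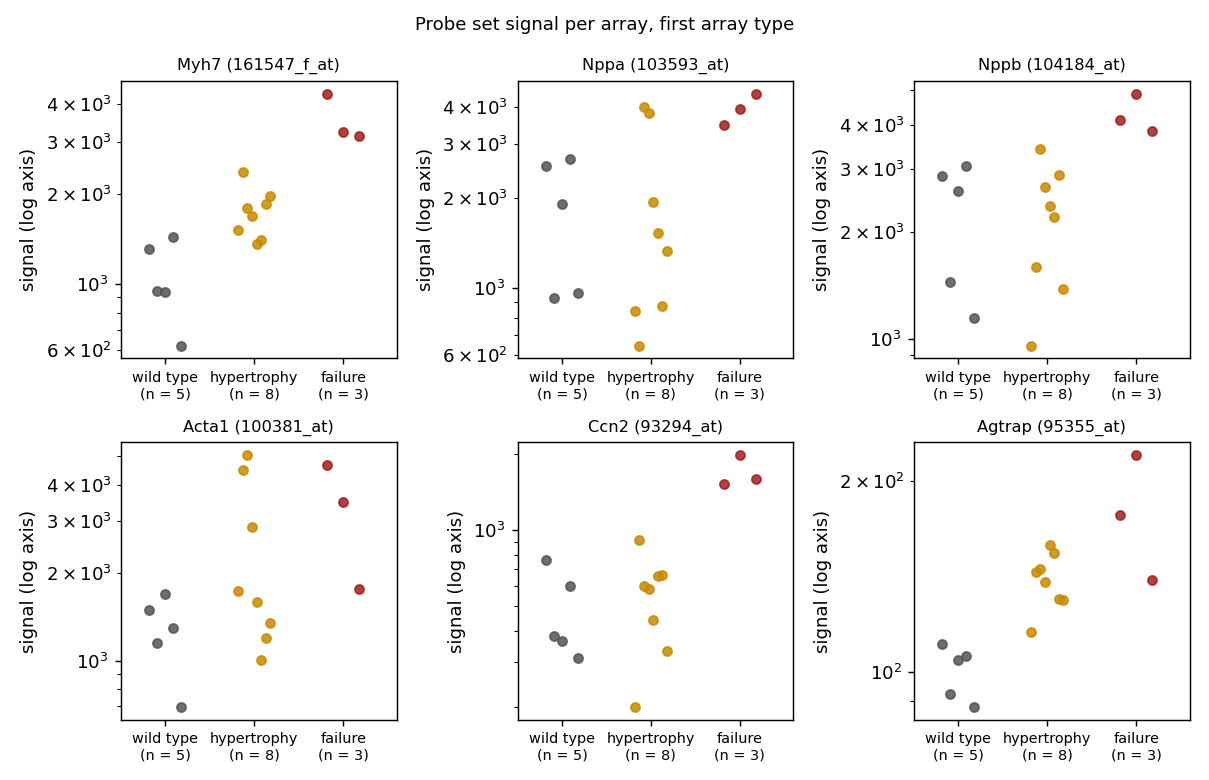
Signal (log axis) of 6 probe sets on every array of the first type, 1 point per array. For Myh7, Nppa, Nppb, Acta1, Ccn2 and Agtrap the 3 failure arrays lie above the 5 wild type arrays; Myh7 (dimmer probe set) and Agtrap passed the test.

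Of the gene lists, 4 were higher and 4 lower with camera. Hypertrophy and fetal markers had a median log2 change of 0.63 (adjusted p = 5.6e-05 and adjusted p = 0.724 with an estimated correlation), and 7 of 14 measured members were higher adjusted over the list alone. None of the 13 members was called in the probe set used for this test, which for Myh7 is the brighter one; the remaining member, Xirp2, lies on the second type and was called there. The failure means (9.70, 9.77 and 9.95) lay above the wild type range of 8.73 to 9.60. Myl7 differed by 1.60 ± 0.42 and Ankrd1 by 0.89 ± 0.26. Extracellular matrix genes had a median of 0.44 (adjusted p = 4.0e-08 and adjusted p = 0.724 with an estimated correlation), with 0 of 32 called and 13 higher adjusted over the list alone. Ccn2, the connective tissue growth factor gene, differed by 1.88 ± 0.39, biglycan (Bgn) by 1.61 ± 0.38, Mgp by 1.23 ± 0.25 and elastin (Eln) by 0.80 ± 0.19 (log2, SE). Failure replicate 3 had a matrix list mean of 8.13, within the wild type range, against 9.08 and 9.09 in replicates 1 and 2. It is also the only failure array with Xist below Eif2s3y. Complement and acute phase genes had a median of 0.42 (adjusted p = 0.0165 and adjusted p = 0.724 with an estimated correlation), with 0 of 11 called and 1 adjusted over the list alone. Clu differed by 1.06 ± 0.21, C1qb by 0.87 ± 0.37, Saa3 by 0.49 ± 0.18 (0.31 without failure replicate 2) and C1qc by 0.45 ± 0.20 (0.29 without failure replicate 1). The list mean was 8.09, 8.01 and 7.57 in failure replicates 1, 2 and 3, the last within the wild type range of 7.39 to 7.63. Fibroblast markers had a median of 0.38 (adjusted p = 0.0377 and adjusted p = 0.777 with an estimated correlation), with 0 of 13 called and 2 adjusted over the list alone. Mfap5 differed by 1.26 ± 0.28, Col1a1 by 1.24 ± 0.45 (0.77 without failure replicate 2, and 1.61 times as large without replicate 3), Pi16 (on the second type, outside the test) by 0.90 ± 0.24 and Gsn by 0.60 ± 0.23. The fibroblast list mean was 8.95 and 8.91 in failure replicates 1 and 2 but 7.90 in replicate 3, below every wild type array (7.99 to 8.26).

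Respiratory chain genes had a median of -0.33 (adjusted p = 1.4e-14 and adjusted p = 0.724 with an estimated correlation), with 45 of 48 members negative, 0 called and 0 adjusted over the list alone. Cox7a1 differed by -0.89 ± 0.23, Uqcrc2 by -0.75 ± 0.24, Atp5k by -0.65 ± 0.21 and Atp5pb by -0.64 ± 0.19 (log2, SE). The failure means (10.27, 10.34 and 10.50) lay below the wild type range of 10.51 to 10.84. Fatty acid oxidation genes had a median of -0.16 (adjusted p = 0.000933 and adjusted p = 0.724 with an estimated correlation), with 0 of 28 called and 3 lower adjusted over the list alone. Hsd17b10 differed by -0.75 ± 0.25, Acaa2 by -0.70 ± 0.18, Hadh by -0.58 ± 0.17 and the receptor gene Ppara by -0.46 ± 0.14. All 3 failure means of this list (9.07, 9.16 and 9.14) lay within the wild type range of 9.03 to 9.48. Glycolysis genes had a median of -0.09 and a mean of -0.23 (adjusted p = 0.00128 and adjusted p = 0.724 with an estimated correlation), with 0 of 20 called and 2 lower adjusted over the list alone. Ldhb differed by -0.85 ± 0.21, Eno3 by -0.75 ± 0.19, Hk2 by -0.59 ± 0.20 and Slc2a1 by 0.39 ± 0.19. Its mean was 9.54 and 9.62 in failure replicates 1 and 2, below wild type, and 10.01 in replicate 3, within the wild type range of 9.76 to 10.04. Tricarboxylic acid cycle genes had a median of -0.17 (adjusted p = 0.00463 and adjusted p = 0.890 with an estimated correlation), with 0 of 21 called and 0 adjusted over the list alone. Cs differed by -0.43 ± 0.16, Idh3a by -0.42 ± 0.19 (-0.21 without failure replicate 1), Suclg1 by -0.41 ± 0.25 and Fh1 by -0.35 ± 0.19. Here too failure replicate 3, at 10.09, lay within the wild type range of 9.82 to 10.18, and replicates 1 and 2, at 9.62 and 9.78, below it. With the Actb ratio as a covariate, chosen after seeing the data, Cox7a1 was -0.57, Uqcrc2 -0.46, Atp5k -0.38, Ppara -0.29, Cs -0.21, Suclg1 -0.18 and Idh3a -0.16, and of the higher members C1qb was 0.38 and C1qc 0.29.

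None of the 8 lists passed exact permutation of the list means after adjustment (smallest adjusted p = 0.402). The design allows no p under 0.0179 here, so after adjustment over 90 tests a list could hardly pass, and this result says little. Unadjusted, 4 of the 30 lists had an exact permutation p under 0.05, among them the respiratory chain at 0.0357. Beside these lists, the Actb ratio was 0.960 ± 0.173 (SD, n = 3) in failure and 0.623 ± 0.0819 (SD, n = 5) in wild type. The other 22 lists did not pass, with medians from -0.24 to 0.29. Among them, endothelial markers had a median of 0.18 (adjusted p = 0.135), atrial markers 0.29 (adjusted p = 0.255), macrophage and neutrophil markers 0.04 (adjusted p = 0.826) and smooth muscle and pericyte markers 0.02 (adjusted p = 0.993).

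The third comparison set failure against hypertrophy, both transgenic. On the second array type 2 of 7004 probe sets passed, both higher in failure. Ralgapa2, a regulator of Ral GTPases, rose by 1.55 ± 0.25 (log2, SE), from 110 ± 27.1 (SD, n = 8) to 316 ± 55.1 (SD, n = 3), and Mtap, an enzyme of methionine salvage, by 0.93 ± 0.15, both with adjusted p = 0.0441. Without hypertrophy replicates 6 and 7 the count was 0, while Ralgapa2 differed by 1.57 (adjusted p = 0.0667) and Mtap by 0.99 (adjusted p = 0.0605), about as much as with them. The count was 12 and 13 without hypertrophy replicate 1 or 2, 1 without wild type replicate 5, and 0 without any other wild type array, any failure array or hypertrophy replicate 3, 4, 6 or 8. Each of the calls was lost in 12 of the 16 fits that left out 1 array.

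On the first type none of 6980 probe sets passed in limma, and 702 had an unadjusted p under 0.05, against 349 by chance. The 6 smallest p-values belonged to Kif5b, Plp2, Cebpd, Mkln1, Hopx and Sod1, with log2 differences of 2.32 ± 0.39, 0.60 ± 0.11, 1.12 ± 0.22, -0.97 ± 0.23, -0.97 ± 0.23 and -0.68 ± 0.17 (SE). Mkln1 was -0.58 without failure replicate 3. Leaving out failure replicate 3 gave 24 calls, hypertrophy replicate 3 gave 6, and wild type replicate 5 or hypertrophy replicate 8 gave 1. Nppa differed by 1.37 ± 0.50, Nppb by 1.07 ± 0.35, Acta1 by 0.59 ± 0.45 and Myh7 by 0.43 ± 0.12 and, in its dimmer probe set, 1.04 ± 0.22 without passing. Acta1 was 0.28 and 0.99 without failure replicates 1 and 3, 0.29 without hypertrophy replicates 6 and 7, 0.23 with the Actb ratio and 0.16 with Xist. Myh6 differed by -0.08 ± 0.10, Atp2a2 by 0.03 ± 0.08 and Agtr1a by -0.06 ± 0.16. Quantile and median scaling turn the sign for Atp2a2, as does leaving out failure replicate 1 (-0.0097), which also turns Agtr1a to 0.086. Agtr1a is also turned without hypertrophy replicate 4 (0.013) and with the Actb ratio (0.14), and Myh6 was -0.25 with quantile scaling.

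With camera, 5 lists were higher in failure than in hypertrophy. Fetal markers had a median of 0.59 (adjusted p = 0.000113 and adjusted p = 0.724 with an estimated correlation), with 0 of 14 called and 7 adjusted over the list alone; Myl7 differed by 1.51 ± 0.39 and Enah by 1.10 ± 0.27. Matrix genes had a median of 0.43 (adjusted p = 1.5e-05 and adjusted p = 0.724 with an estimated correlation), with 0 of 32 called and 10 adjusted over the list alone. Ccn2 differed by 1.75 ± 0.36, Fn1 by 1.13 ± 0.26, Tgfb3 by 0.88 ± 0.23 and Eln by 0.78 ± 0.17. Complement genes had a median of 0.42 (adjusted p = 0.0206 and adjusted p = 0.724 with an estimated correlation), with 0 of 11 called and 1 adjusted over the list alone. Clu differed by 0.99 ± 0.20, Serpina3n by 0.94 ± 0.37, C1qb by 0.93 ± 0.35 and Saa3 by 0.41 ± 0.16 (0.23 without failure replicate 2). Endothelial markers had a median of 0.21 (adjusted p = 0.0345 and adjusted p = 0.724 with an estimated correlation), with 0 of 12 called and 2 adjusted over the list alone; Vwf had signals of 239.7 ± 78.3 (SD, n = 3) and 119 ± 32.2 (SD, n = 8), and Tie1 differed by 0.42 ± 0.11, Nos3 by 0.40 ± 0.17 and Flt1 by 0.30 ± 0.14. Proteasome genes had a median of 0.18 (adjusted p = 0.0345 and adjusted p = 0.950 with an estimated correlation), with 0 of 24 called and 0 adjusted over the list alone. Psmd4 differed by 0.51 ± 0.28, Psma1 by 0.45 ± 0.20, Psmd7 by 0.35 ± 0.16 and Psmc1 by 0.30 ± 0.16.

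Respiratory chain genes were lower, with a median of -0.12 (adjusted p = 2.0e-05 and adjusted p = 0.777 with an estimated correlation), 0 of 48 called and 0 adjusted over the list alone. Cox7a1 differed by -0.72 ± 0.22, Atp5k by -0.43 ± 0.20, Ndufa8 by -0.39 ± 0.17 (-0.24 without failure replicate 1) and Atp5g2 by -0.35 ± 0.16. Fatty acid oxidation genes had a median of -0.13 (adjusted p = 0.000530 and adjusted p = 0.724 with an estimated correlation), with 0 of 28 called and 1 lower adjusted over the list alone. Acot2 differed by -0.77 ± 0.27, Hadh by -0.65 ± 0.16, Acaa2 by -0.52 ± 0.17 and Eci1 by -0.45 ± 0.20. In the matrix and complement lists failure replicate 3, at 8.13 and 7.57, lay within the hypertrophy ranges of 7.59 to 8.67 and 7.25 to 7.66, and replicates 1 and 2 above them. In the respiratory chain and fatty acid lists all 3 failure means (10.27, 10.34, 10.50 and 9.07, 9.16, 9.14) lay within the hypertrophy ranges of 10.12 to 10.86 and 8.98 to 9.62, with exact permutation p of 0.382 and 0.309. With the Actb ratio as a covariate Cox7a1 was -0.47, Atp5k -0.22, Atp5g2 -0.089, Psmd4 0.21, Psma1 0.11, Nos3 0.14, C1qb 0.53 and Serpina3n 1.53, and without hypertrophy replicates 6 and 7 Psmd4 was 0.31 and Psma1 0.29. Within the hypertrophy ranges of the fetal (8.41 to 9.92), proteasome (7.77 to 8.56) and endothelial (7.14 to 7.88) lists lay 2, 2 and 1 of the 3 failure arrays. The Gapdh and Actb ratios were also higher in failure than in hypertrophy, at 0.995 and 0.960 against 0.785 and 0.701. The other 23 lists did not pass, with medians from -0.11 to 0.26.

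The hypertrophy and failure changes were then set against each other. Across probe sets, which are not independent replicates, they correlated with r = 0.450 on the first type and 0.546 on the second. Both comparisons use the same wild type arrays, and 100 simulations of unchanged groups gave median r of 0.434 and 0.460. Of these simulations 48 and 39 were at or above the observed values. They drew residuals from all 16 arrays pooled, so hypertrophy arrays of wide spread could stand in for wild type ones. For this reason they do not decide whether the changes are similar. The covariances were 0.0204 and 0.0350, against simulated means of 0.0135 and 0.0183; 24 and 13 of the 100 simulations reached the observed ones. With the wild type arrays split between the comparisons, the median r was 0.188 and 0.299. Over the 10 splits r ranged from 0.0788 to 0.279 on the first type and from 0.217 to 0.412 on the second. It was positive in each, but the splits reuse the same arrays and are not independent. On the second type 3 probe sets were called higher in both comparisons (Styx, Slc13a1 and 1 without a gene name) against 0.0286 for independent lists, and 1 was called lower in both (Med28) against 0.00143. Leaving out 1 array gave 3 to 8 higher in both, and 0 to 2 lower in both, with 0 in 7 of the 16 fits. In failure Med28 differed by -0.81 (adjusted p = 0.0324), and its change stayed between -0.90 and -0.74 leaving out 1 array. These values ignore the shared wild type arrays. On this type, in 100 rearrangements of the residuals that keep the wild type arrays shared, 0 probe sets were called in both comparisons, but only 9 of the 100 had any call, so this covers unchanged groups alone. With 2 wild type arrays used for hypertrophy and the other 3 for failure, in separate fits of the groups compared, each of the 10 divisions left 2 called higher in both and 0 called lower.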

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

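The tests of the Gapdh ratio, the Styx signal, atrial and cell type markers and Xist were chosen after the results were seen. The splits of the arrays were not. Predictions for the Actb trend and the Styx neighbours were written before those tests, but the respiratory chain and Styx patterns they concern came from these results.

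Among 194 groups of 5 or 8 arrays examined for a single array far from the rest, 11 stood out by Dixon's ratio, and chance gives about 9.7. In wild type arrays the 18S ribosomal control of replicate 2 was the highest on both array types, at 6297 and 6194 against 925.7 and 825.0 for the next (ratios 0.893 and 0.903), and the Actb ratio of replicate 5 was the highest on the second type (0.845). Also in wild type, replicate 5 was highest for Kif5b (0.817) and lowest for Pfkp (0.828), and replicate 2 was lowest for Mtap (0.725) and Psmd7 (0.756). The Styx ratio of 1 reflects 4 wild type arrays set to the floor and replicate 1 just above it. In hypertrophy, replicate 1 was lowest for Xirp2 (0.557) and Serpina3n (0.602), and replicate 7 for Psma1 (0.554).

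Other splits of the same arrays show how often regrouping gives as many calls. For failure against wild type the real split was the only 1 of 56 with as many calls. This held on the first type (10, highest other 0) and on the second (25, highest other 0), and it is the smallest share that 56 splits allow. The types may carry the same RNA, so these are not shown to be independent results. For hypertrophy against wild type on the second type 3 of 100 splits gave 12 or more calls, the highest other 157. These 100 are the real split and a random draw from the 1287 possible, and those for failure against hypertrophy were drawn likewise. The shares of 1 in 56 and 3 in 100 lie under 0.05 but are not adjusted for the number of comparisons. That of 3 in 100 is an estimate from the draw, and the share over all splits could be larger. Samples may also not be separate animals, so the shares do not exclude chance. For failure against hypertrophy on the second type the share was larger (2 calls, 6 of 100, highest other 97). On the first type hypertrophy against wild type and failure against hypertrophy had 0 calls, which all 100 of 100 splits reach by construction, so the splits say nothing about chance there; the highest others were 163 and 172. On both types the highest split against hypertrophy set hypertrophy replicates 4, 6 and 7 apart, and the highest against wild type set hypertrophy replicates 4, 5, 6 and 7 with wild type replicate 2 apart. Both hold the 2 arrays of low Gapdh ratio and call far more than the groups do. They are the highest of many splits, whose median count was 0, and the same splits were used on both types. Any call came in 6 and 3 of 100 splits for hypertrophy against wild type, on the first and second type. For failure against hypertrophy it came in 8 and 14. A structure of the samples other than the groups is possible but was not tested.

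Nor can chance be excluded for the numbers of gene lists past the camera test. For hypertrophy against wild type 65 of 100 splits gave 3 lists or more (highest other 10), for failure against wild type 13 of 56 gave 8 or more (highest other 12), and for failure against hypertrophy 14 of 100 gave 7 or more (highest other 12).

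The first pattern weighed is the lower respiratory chain list. Without the 2 arrays of low Gapdh ratio the hypertrophy difference of the list mean was -0.21 rather than -0.19, with an exact permutation p of 0.0866, so the difference did not shrink without them, but with this p the data do not decide whether it exceeds the spread between arrays. The list mean and the Actb ratio within groups, over 16 arrays, had r = -0.325 (permutation p = 0.343) and rho = 0.0735 (permutation p = 0.812). Without the 2 arrays farthest from the median ratio r was 0.585, so the negative value rests on them, and an effect of RNA integrity cannot be told apart from the groups. A change with hypertrophy or failure itself may equally underlie the list and stays open.

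The second pattern is the Styx probe set. The lowest of the 11 transgenic signals was 34.3 times the highest wild type signal, and failure differed from hypertrophy by -0.20 (log2, adjusted p = 0.807). A transcript sequence carried by the transgene would give such values. The same values prompted the idea, so they do not test it, and it stays a hypothesis. Another Styx probe set was above the floor on every array, though near it, with a median signal of 49.2. It changed by -0.19 in hypertrophy and -0.17 in failure (log2, upper confidence limits 0.17 and 0.28). The third was at the floor on all 16 arrays, with deposited signals of 7.43 to 31.6. A rise of the whole gene as large as that of the called probe set would have lifted both, so these values argue against it. This holds only if these dim probe sets detect the transcript, which was not tested. The 20 measured genes nearest to Styx in GRCm38.p6 had a median absolute change at percentile 93.9 of random groups, and 0 of their 29 probe sets passed, which does not decide on an altered region. The probe sequences were not used here.

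The third pattern is the higher matrix and fetal lists in failure. Of the atrial markers Myl7, Myl4 and Sln, Sln had no tested probe set on the first type, Myl7 differed by 1.60 ± 0.42 and Myl4 by -0.61 ± 0.87 (log2, SE), and 0 of them had an interval ending below the matrix median, so atrial tissue stays open. Between wild type and failure, the mean of fibroblast markers rose by 0.36 (log2) more than that of the other cell types (exact permutation p = 0.250). The mean of the other types rose by 0.10 (exact permutation p = 0.0714). Of 21 measured sarcomere and Z-disc genes, 13 were positive and 8 negative in failure, with 0 called. A lower share of cardiomyocytes stays open. Within groups, arrays with Xist above Eif2s3y had a matrix list mean higher by 0.35 (exact permutation p = 0.136) and a fetal mean differing by -0.02 (exact permutation p = 0.926), and failure replicate 3, lowest of the failure arrays for the matrix list, is the only one of them with Xist below Eif2s3y, so sex may contribute to the matrix list and cannot be told apart here. A response to failure itself remains among the open explanations.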

How the results depend on the processing

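The fits with the Gapdh ratio, Actb ratio or Xist as covariates, those without the 2 arrays of low Gapdh ratio, and the permutation of list means were chosen after the data were seen. Styx, Slc13a1 and Med28 in hypertrophy against wild type, and Styx in failure against wild type, passed in each of 16 fits leaving out 1 array and 13 other settings, not counting the replicate block; the dimmer Myh7 probe set lost its call in failure only without failure replicate 1. The other calls of genes named by the rule were each lost without at least 4 single arrays. Of those named outside it in failure against wild type, Slc13a1 was kept without each of 16 arrays, and Clip1, Tgfbr1 and Med28 were lost without 10, 9 and 7 of them, with log2 changes staying at 1.45 to 1.82, 0.72 to 0.88 and -0.90 to -0.74. The calls shared by both comparisons with wild type on the second type (3 higher, 1 lower) were 3 to 8 and 0 to 2 leaving out each array. No called change of a gene named by the rule moved by over 1.5 times or turned in any of these fits. Dim probe sets near the floor limit what can be seen. Hypertrophy arrays enter failure against wild type only through the shared estimate of spread. Leaving some or all of them out keeps its log2 changes and moves its counts through that estimate alone. The cause of the other differences below was not tested.

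For failure against wild type on the first type (10 calls) the count was 30 with quantile scaling, 32 with median scaling, 6 and 27 with floors at the 5th and 40th percentile, 22 without a filter, 17 with the stricter filter, 1002 with array weights, 122 with only the groups compared, 17 adjusted over both types, 34 without the low Gapdh arrays, and 28 and 42 with the Gapdh and Actb ratio. On the second type (25 calls) it was 46 with the 40th percentile floor, 55 without a filter, 43 with the stricter filter, 428 with array weights, 193 with only the groups compared, 70 without the low Gapdh arrays, and 71, 81 and 12 with the Gapdh ratio, Actb ratio and Xist. Array weights were highest for failure replicate 2 (3.45 on the first type) and lowest for hypertrophy replicate 1 (0.253).

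For hypertrophy against wild type the first type (0 calls) gave 1 without a filter; the second (12 calls) gave 22 with array weights and 7 both without the low Gapdh arrays and adjusted over both types. For failure against hypertrophy the first type (0 calls) gave 3 with the 40th percentile floor, 10 without a filter, 2 with the stricter filter and 274 with array weights. The second (2 calls) gave 12 with the 40th percentile floor and 12 without a filter, 30 with array weights, 5 with the Gapdh ratio, and 0 with only the groups compared, without the low Gapdh arrays, with the Actb ratio, with Xist or adjusted over both types. Leaving out each array gave 0 to 1 and 5 to 25 calls for hypertrophy against wild type, 0 to 51 and 4 to 79 for failure against wild type, and 0 to 24 and 0 to 13 for failure against hypertrophy, on the first and second type.

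With an estimated correlation, fry, exact permutation of list means or the second array type, 0 lists passed in each comparison. For failure against wild type the permutation allows no p under 0.0179, so after adjustment it could hardly pass. Lists past the threshold for hypertrophy against wild type (3) were 5 with Xist, and 2 to 6 leaving out each array (6 without wild type replicate 2); for failure against wild type (8) they were 5 with the Actb ratio, and 4 to 10 (4 without failure replicate 1). For failure against hypertrophy (7) they were 4 with the stricter filter and 12 with array weights. In list tests the variance trend was used without robust estimation, which camera lacks. The median r of the similarity was 0.188 and 0.299 with split wild type arrays.

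With the replicate number as a block, the counts were 3 for hypertrophy against wild type on the second type, 3 and 6 for failure against wild type, and 0 for failure against hypertrophy on the second type, with 5 lists for hypertrophy against wild type. Med28 lost its call in hypertrophy against wild type there (adjusted p = 0.104) with a log2 change of -0.81, and in failure against wild type (adjusted p = 0.133). Of the genes named by the rule, 3 lost their calls in hypertrophy against wild type (Med28, Vgll4 and Acat1). In failure against wild type 10 did, and in failure against hypertrophy 2. Their changes were 0.892 to 1.07 times those without the block. The labels do not say that the numbers pair the samples, and the correlations do not settle it. Same-numbered arrays of hypertrophy and wild type had deviations correlating between -0.11 and 0.36 on the first type, and 2 of 5 hypertrophy arrays correlated best with their own number. On the second type 0 of these 5 pairs exceeded 0.1, while 2 of 3 pairs of failure and hypertrophy did. Under the block the log2 difference turned to 0.089 for Nppa in hypertrophy against wild type, and to -0.14 for Acta1 and 0.0032 for Agtr1a in failure against hypertrophy.

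Signs also turned for values that were never called. In hypertrophy against wild type Nppa was 0.085 with array weights, 0.025 without the low Gapdh arrays, and -0.31 to 0.073 leaving out each array. Nppb was 0.030 with quantile scaling, 0.071 with the Actb ratio, and -0.24 to 0.13. Myh6 was 0.040 with quantile and 0.0018 with median scaling, 0.0049 without the low Gapdh arrays, 0.0026 with Xist, and -0.033 to 0.029. Pfkp was -0.025 to 0.14 leaving out each array. Atp2a2 was -0.0064 with quantile scaling in failure against wild type; against hypertrophy it was -0.16 with quantile and -0.033 with median scaling, and -0.0097 to 0.078. Agtr1a in failure against hypertrophy was 0.14 with the Actb ratio and -0.19 to 0.086 leaving out each array.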

Other observations

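The comparison of same-numbered arrays of the 2 types was chosen after the data were seen; the list values are from the planned tests. Several lists that did not pass the camera test held members past the threshold within their list. In failure against wild type, immediate early genes had a median log2 change of 0.23 with 1 of 18 past the threshold adjusted over the list alone, endothelial markers had 3 of 12, and atrial markers 2 of 7. Creatine kinase and adenylate phosphotransfer genes had a median of -0.24, with 1 of 8 lower adjusted over the list alone and a camera adjusted p of 0.0543. In failure against hypertrophy, antioxidant and metallothionein genes had 3 higher and 1 lower of 19 adjusted over the list alone, with a median of -0.04.

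Arrays of the same number on the 2 array types were compared by their deviations from the group means. Over 855 genes measured on both types, the median correlation of these deviations was 0.0587 for the same number and -0.0023 otherwise (permutation p = 5.0e-05). The relation was thus weak over these genes, which different probe sets measure on the 2 types. For single arrays it ranged from -0.047 to 0.141, and 5 of 16 matched their own number best. Over 20 control probe sets the median was 0.843 for the same number, with a range of 0.259 to 0.980, and 10 of 16 matched best. Hypertrophy replicates 6 and 7 had Gapdh ratios of 0.379 and 0.0414 on the second type, and of 0.468 and 0.0487 on the first. Same-numbered arrays may therefore carry the same RNA, so a result found on both types is not shown to be independent.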
